A study of Bacillus subtilis with 2 samples.

How the data were processed

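The series holds 2 two-colour arrays of 60-nt oligonucleotides, 1 per strain, each comparing untreated with IPTG-induced cells of Bacillus subtilis that carry an IPTG-inducible sigV gene. Per the labels, RNA was treated with DNase, reverse transcribed and labelled with Alexa Fluor 555 (untreated) or Alexa Fluor 647 (induced). The labels speak of independent replicate cultures, whereas the tables hold 1 ratio per gene and strain, and whether it joins several cultures or spots is not given in the sources used here. No dye swap was among the data used. The scanner, the background correction and the normalization are likewise not given in the sources used here.

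The deposited values are log10 ratios of the 2 channels. The base follows from the values, since 96.7% on each array equal the base 10 logarithm of a ratio of whole numbers (denominator up to 12000, tolerance 6e-10), against 20.9% and 20.0% of values moved at random on the wild type array and the other array. The numerator is not stated, and the direction was taken as induced over untreated, as the likely one. The complete table has 4128 rows, of which 4106 are gene probes, 1 per gene, and 22 are control probes named for E. coli genes, BMV RNA or random sequences. A second deposited table repeats the gene values to within 1.67e-08. In the wild type 14 genes have no value (6 with a zero denominator and 8 with the logarithm of 0 or less), and in the strain lacking the ECF sigma factors 8 (2 and 6). They were left out there.

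The values were converted to log2 and used without further normalization. A gene was counted at a ratio of at least 2-fold in either direction. With 1 array per strain there is no replicate check, the number of arrays limits the precision, and no p-value is given. Intensities were not used here. In their place the reduced whole-number ratio was read, whose numbers are lower bounds of the signals in an unknown unit because a common factor is lost. A bright spot can thus appear dim where its numbers share a large factor. A spot was taken as above control level if the number of the brighter channel was over 137, or if no whole-number ratio was found. Of the 44 control values 43 are at or below this number, and the highest is 976, from 1 random-sequence spot on the wild type array. This reading was chosen after the data were examined.

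The 24 gene lists, written from general knowledge, the 2-fold limit and the rule for named genes were fixed before the data were examined. The rule takes sigV, its operon and the other ECF sigma factor genes, the 12 highest and 8 lowest genes of each strain, the 5 largest and 5 smallest differences between strains among genes at least 2-fold apart in either strain, and up to 4 members with the largest ratio from each list. Lists were matched by symbol, which found 477 of 560 members, and 3036 of the 4106 array symbols are in the RefSeq gene table used for names and neighbours. The array carries older symbols for many genes, so a table of 70 older symbols written from general knowledge was used as an alternative. For each list the median log2 ratio and the percentile of the median among 10000 random gene lists of the same size were taken. Intervals of list medians are 95% binomial intervals from the ranked values of the members. The random lists were not matched on signal, except in an alternative. Members of an operon are not independent, and the percentile describes these arrays only.

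Between strains, the difference of the log2 ratios was taken per gene, and overlaps are set beside the product of the 2 counts over the genes measured. The 2 arrays share no channel, so no shared control had to be considered. They do share the dye order, and a dye or probe effect common to both would raise the overlaps above this product. Exact binomial intervals (Clopper-Pearson, 95%) are given for shares of control spots. Alternatives were limits of 1.5-fold and 3-fold, centring on the median of all genes or of the genes above control level, scaling both arrays to 1 robust spread, the second table, keeping control probes, leaving out the ECF sigma factor genes with their operons, list means, leaving out shared list members, 1 value per run of neighbouring members, random runs of neighbouring genes, spots above control level, older symbols, random lists matched on signal, and readings of either channel under 137 raised to 137 before the ratio was taken. The last was added after the results were seen, and it sets genes with both readings under 137 to a ratio of 1. For the SigW and SigM lists the genes above control level on both arrays were also scaled to 1 standard deviation, chosen after the results were seen.

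Calculations were made in Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and plots with matplotlib 3.10.9. The steps were tested on simulated data. From pairs of whole numbers drawn like those of the 3955 and 3961 genes of the wild type and the deletion strain, 99.97% were read back on each array. All of 100 genes raised 4-fold and all of 100 genes lowered 4-fold were counted on both arrays. These genes had untreated numbers over 100, and the added noise was below the robust spread of either array. The counting of dim spots was thus not tested. Of 100 unshifted lists of 40 genes, 4 and 5 fell outside the central 95% of random lists.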

Results

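Transcript levels of Bacillus subtilis were compared before and after induction of sigV, the gene of an extracytoplasmic function (ECF) sigma factor that responds to lysozyme. ECF sigma factors are RNA polymerase subunits that direct transcription to small sets of cell envelope genes, and their target promoters overlap. The inducible copy of sigV was placed in wild type cells and in a strain lacking all 7 ECF sigma factors. Each strain was grown to an OD600 of about 0.6, divided, and sampled 20 min after IPTG was added to a part of the culture. Each strain was measured on 1 array with 2 channels, untreated cDNA in Alexa Fluor 555 and induced cDNA in Alexa Fluor 647. With 1 ratio per gene and strain there is no replicate error, so that no test between conditions could be made and all differences below are sizes on these 2 arrays. A ratio was obtained for 4092 of 4106 genes in the wild type and for 4098 in the strain lacking the ECF sigma factors.

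The labels do not state which channel is the numerator of the ratio. The direction used throughout, induced over untreated, is the likely one, because the probe of the IPTG-driven sigV has a strongly positive value on both arrays. The order in which the labels name the channels does not settle the direction. Since sigV was used to choose the direction, the sign of its ratios below is not a separate result. Signal was read as far as the ratios allow it, from the reduced whole-number ratio that most values equal. A spot whose brighter channel had a number above 137 lay above 43 of the 44 control spot values of both arrays, and is called here a spot above control level. There were 2446 such genes in the wild type, 2680 in the strain lacking the ECF sigma factors and 2154 on both arrays. The median log2 ratio of these genes was -0.22 in the wild type and -0.20 in the other strain, against -0.01 and -0.06 over all genes, so that a value near -0.2 is the middle of the well measured genes. Many large ratios of genes above control level still rest on an untreated reading of 137 or less, namely 51 of the 104 at least 2-fold higher in the wild type and 89 of the 166 in the other strain. The size of such a ratio is poorly fixed, and for genes named with large ratios a second one, the raised ratio, is given below, in which readings under 137 are raised to 137. Besides the genes that the rule fixed before the data were examined selected, further members of the gene lists and genes above control level are named below, and these were chosen after their values were seen.

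**Figure D1:**
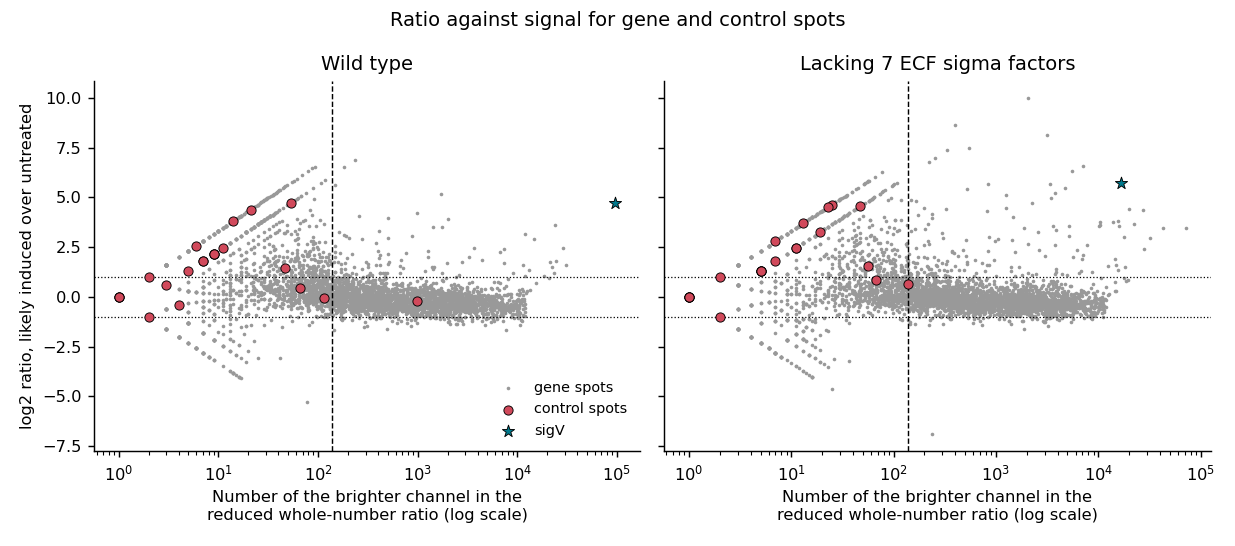
Log2 ratio (likely induced over untreated) of each gene spot and control spot with a whole-number ratio, against the number of its brighter channel (log scale), for the wild type (left) and the strain lacking 7 ECF sigma factors (right). The dashed line marks 137 and the dotted lines mark a 2-fold difference. Of the 22 control spots, 13 in the wild type and 15 in the other strain were at least 2-fold higher.

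The wild type array asked which genes follow sigV when the other ECF sigma factors are present. The sigV probe was 26.2-fold higher in induced cells. The rest of its operon was higher with it, by 11.6-fold for yrhM, which encodes the anti-sigma factor RsiV, by 8.86-fold for yrhL, which encodes the peptidoglycan O-acetyltransferase OatA, and by 12.2-fold for yrhK. Outside the operon, ywaC, which encodes a small alarmone synthetase, was 17.1-fold higher, and ywnJ was 15.0-fold higher. The undecaprenyl pyrophosphate phosphatase gene ywoA (bcrC) was 7.62-fold higher, the D-alanine ligase gene ddl 5.58-fold, the lipid II flippase gene ydaH (amj) 5.51-fold and murF, which encodes the next enzyme of peptidoglycan precursor synthesis after Ddl, 3.07-fold. Untreated readings were 137 or less for ywaC, yrhM and ywnJ, and the raised ratios were 1.87-fold, 10.4-fold and 14.7-fold.

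The list of genes reported for SigM, which governs cell wall synthesis and division genes, held most of these. Of its 57 measured members, 20 were at least 2-fold higher in the wild type, 2 were at least 2-fold lower and the others lay between. With readings raised to 137 these counts were 18 and 0, with a median of 0.58. Its median log2 ratio was 0.70 (95% interval of the median over members 0.28 to 0.94), above all 10000 random lists of the same size (percentile 100). Members of the operon of maf, radC, mreB, mreC, mreD, minC and minD, for cell shape and division site placement, ranged from 3.68-fold higher for radC and 3.38-fold for maf to 1.70-fold for mreD. In the list for D-alanylation and modification of envelope polymers, called the D-alanylation list below, the 6 of 7 members found by symbol were pbpX and the dlt operon, which serves to add D-alanine to teichoic acids, and the member oatA is on the array as yrhL. Of the 6 members 4 were at least 2-fold higher, with dltE at 3.0-fold, pbpX at 2.89-fold, dltC at 2.29-fold and dltD at 2.03-fold, and the median of 1.11 lay at percentile 96.7. The divisome gene divIC, shared by the SigM and SigX lists, was 2.28-fold higher.

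The SigX list split by membership. Of its 11 members shared with the SigM list or the SigW list, 8 were at least 2-fold higher and 1, yjbC, was at least 2-fold lower. Of its 8 own members none was higher and 1, csbB, was lower by 2.25-fold. The spots of yjbC and csbB were not above control level, and both had a raised ratio of 1. Among those own members were the phospholipid synthesis genes pssA and psd, at log2 ratios of -0.31 and -0.51. The whole list had a median of 0.58 at percentile 98.5 (0 at 59.5 with readings raised), and its own members had a median of -0.47. The SigW list, genes of resistance to peptide antibiotics and membrane-active compounds, was split in the wild type. Of its 53 measured members 5 were at least 2-fold higher and 5 at least 2-fold lower, and the median was -0.03 (95% interval -0.38 to 0.28), at percentile 43.0, while the mean was 0.08. Its place among random lists depends on the setting, with percentile 97.53 against lists matched on signal and 1.35 without members shared with another ECF list. With readings raised 3 members were higher and 4 lower, with a median of 0. Members at or below 0 included sigW itself (2.35-fold lower), yeaA (2.54-fold lower), yknW (log2 ratio -0.01) and the fatty acid synthesis genes fabHA and fabF (both -0.54). The 10 genes of the sigY and ylaC operons had a median of 0.26 at percentile 81.6, or 98.3 against random lists matched on signal. The 3 that were at least 2-fold higher were ylaA, ylaB and ylaC, by 2.83-fold, 3.03-fold and 2.68-fold (raised ratios 2.34-fold, 2.77-fold and 2.68-fold).

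Over all genes of the wild type array, 806 were at least 2-fold higher and 248 at least 2-fold lower. The 12 highest ratios reached 116.5-fold for yqaC, 93-fold for yteT and 91.5-fold for yqiQ, and 9 of these 12 spots, namely the spots of yteT, sigG, bpr, yozN, ynzB, ywcE, ytlD, ysxE and ywcI, were not above control level. The raised ratios of yqaC, yteT and yqiQ were 1.70-fold, 1 and 1.34-fold. The 8 lowest (yteV, ypjP, yngL, yhcX, yusU, cspC, spoIIM and aspB, 14-fold to 38.5-fold lower) were all of this kind. Among the 2446 genes above control level 104 were at least 2-fold higher and 80 at least 2-fold lower, or 147 and 22 when centred on their median. Genes not above control level contributed 702 of the 806, and 42.6% of them were at least 2-fold higher, as were 59.1% of the control spots (exact binomial interval 36.4% to 79.3%), which carry no B. subtilis gene.

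In the strain lacking the 7 ECF sigma factors, the question was which genes respond to SigV in the absence of every other member of the family. The sigV probe was 53.1-fold higher, and yrhM, yrhL and yrhK were 16.0-fold, 12.02-fold and 21.1-fold higher (raised ratio of yrhM 10.6-fold). More of the SigW list was higher here. Of its 54 members 29 were at least 2-fold higher and 3 at least 2-fold lower, with a median log2 ratio of 1.11 (95% interval 0.19 to 2.62), above all random lists (percentile 100). With readings raised to 137 the median was 0, at percentile 59.2, since many members then have a ratio of 1, and 19 members stayed at least 2-fold higher with none lower. The operon yknW, yknX, yknY and yknZ, which protects cells from a toxin of sporulating siblings, was higher by 45.2-fold, 31.6-fold, 9.71-fold and 37.7-fold. The spo0M gene was 79.7-fold higher, ybfO 35.5-fold, yjoB 22.5-fold, yozO 21.5-fold and yndN 18.2-fold. Of these 9 genes only yknY had an untreated reading above 137, and the raised ratios of yknW, yknX and yknZ were 34.6-fold, 25.4-fold and 27.8-fold, of spo0M 40.1-fold, of ybfO 9.07-fold, of yjoB 9.19-fold, of yozO 2.35-fold and of yndN 1.73-fold. The genes of the membrane proteins YqeZ, YqfA and YqfB, of which YqfA is a flotillin, were 12.4-fold, 13.8-fold and 13.8-fold higher, and pspA, of the phage-shock protein family, 11.8-fold.

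The D-alanylation list was higher in all 6 members found by symbol, from 5.19-fold for pbpX to 14.3-fold for dltE, with dltA at 11.2-fold and dltC at 12.9-fold, and its median was 3.47 at percentile 99.97. Of the 57 SigM list members 37 were at least 2-fold higher and 2 at least 2-fold lower, with a median of 1.31 (95% interval 1.06 to 2.07) at percentile 100, and with readings raised 33 were higher and none lower, with a median of 1.24. Among them yqjL was at 1029.5-fold, ywnJ at 284.9-fold, ydaH at 96.4-fold and ywaC at 50.5-fold. The untreated channel of these genes stood at 2, 11, 73 and 67 in the reduced ratio, within the range of the control spots, and the raised ratios were 15.0-fold, 22.9-fold, 51.4-fold and 24.7-fold, so that their order is not fixed. The transition state regulator gene abh was 8.16-fold higher, ddl 6.18-fold and murF 4.24-fold. Of the 10 genes of the sigY and ylaC operons 8 were at least 2-fold higher, among them yxlC at 8.12-fold, yxlF at 7.58-fold, ylaB at 12.8-fold and yxlE at 22-fold, the last from a spot not above control level. The raised ratios were 6.28-fold for yxlC, 1.58-fold for ylaB and 1 for yxlE, and 6 of the 10 genes stayed at least 2-fold higher. The list of genes that share an operon with an ECF sigma factor gene, such as anti-sigma factor genes, had 8 of 11 members at least 2-fold higher in this strain and 2 of 11 in the wild type, with medians of 2.87 and 0.22. With readings raised these were 5 and 2 members and medians of 0.66 and 0.19.

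A part of each ECF list lay near or below 0 in this strain as well. From the SigW list these were ydbS and ydbT (log2 ratios -0.70 and -0.35), yvlA, yvlB, yvlC and yvlD (-0.63, -0.31, -0.36 and -0.10), fabHA and fabF (-0.31 and -0.25) and sppA (-0.35), all on spots above control level. From the SigM list ponA, ytpA, radA and recU had values of 0.05, 0.03, 0.02 and 0.02. The SigX list was at a median of 1.25 with 10 of 19 members at least 2-fold higher and 2 lower, yet its 8 own members again included none that was higher, with a median of -0.48, pssA at -0.50 and psd at -0.46. Its 11 shared members had a median of 3.45. With readings raised the whole list had a median of 0.13, with 9 members higher and none lower.

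Over all genes, 754 were at least 2-fold higher and 240 at least 2-fold lower in this strain. Of the 12 highest (yqjL, yuzE, ywnJ, yheD, yurZ, yqiQ, yqaC, ydaH, spo0M, yjzB, yqbB and ythC), 9 were above control level. Of the 8 lowest (yfkD, ypjP, thdF, cspB, yoaT, prs, ycbF and yutH) only yfkD was above it, at 117.5-fold lower, or 1.72-fold with readings raised, and the raised ratios of yheD, yqiQ and yqaC were 3.96-fold, 1.85-fold and 1.63-fold higher. Among the 2680 genes above control level 166 were at least 2-fold higher and 53 at least 2-fold lower, or 208 and 19 when centred on their median. The probes of the deleted genes sigW, ylaC and sigM were 4.65-fold, 2.55-fold and 14.8-fold higher, sigX was 1.98-fold higher, sigY 1.5-fold higher and sigZ 2-fold lower, with sigM, sigX, sigY and sigZ not above control level, and the raised ratios of sigW and ylaC were 2.85-fold and 2.27-fold. Where these probes lie relative to the deleted parts is not given in the sources used here, so their ratios do not check the deletions. Above control level were 6 of the 7 ECF sigma factor probes in the wild type. In this strain 3 were, those of sigV, sigW and ylaC. The sigY probe had readings of 1159 (induced) and 917 (untreated) in the wild type and 3 and 2 in this strain. Such readings are lower bounds. As a list, the 7 ECF sigma factor genes had medians of 0.34 in the wild type, with 3 higher and 1 lower, and 1.35 in this strain, with 4 higher and 1 lower. With readings raised both medians were 0, with 2 higher and 1 lower and with 3 higher and none lower.

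**Figure D2:**
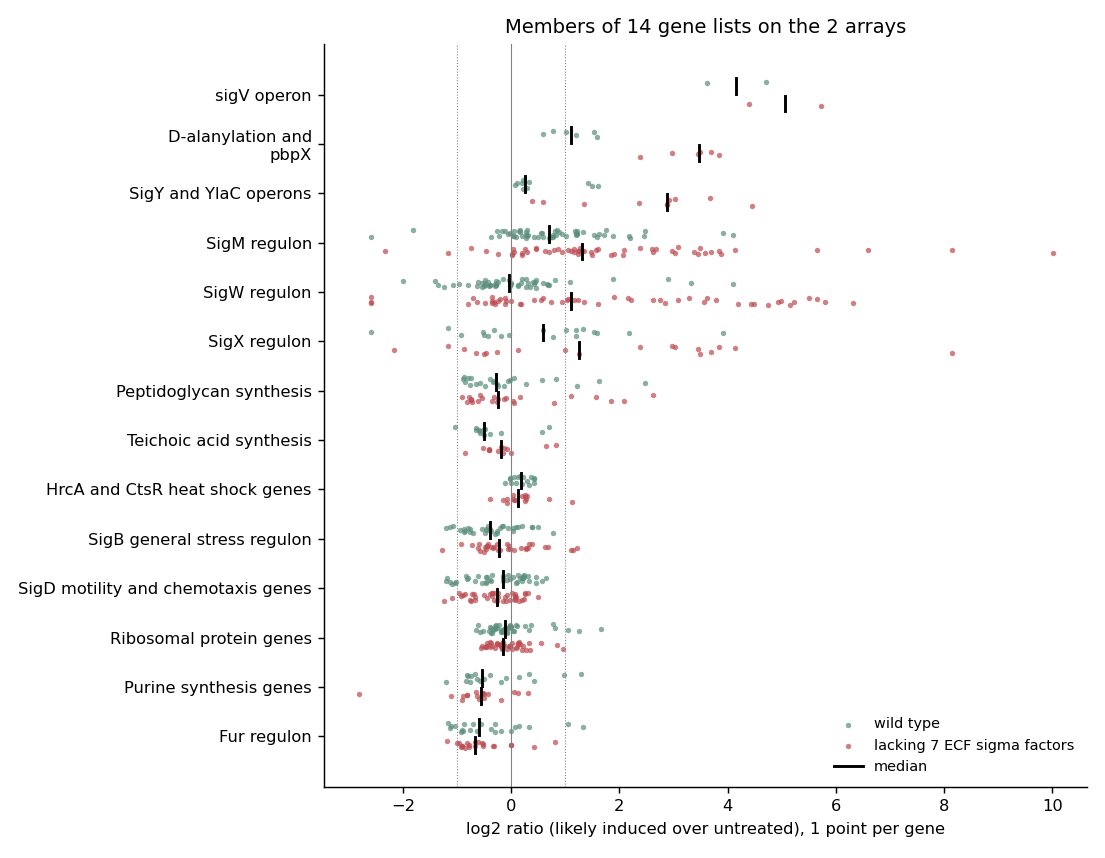
Log2 ratio (likely induced over untreated) of each measured member of 14 gene lists on the wild type array (green, upper row of each list) and on the array of the strain lacking 7 ECF sigma factors (red, lower row), with the median of each row as a black line. The SigW list has a median of -0.03 in the wild type and 1.11 in the other strain, and the D-alanylation list 1.11 and 3.47.

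Set against each other, the 2 strains had many genes at least 2-fold higher in common, with larger ratios of ECF target genes in the strain lacking the family. The ratio of sigV itself was 2.03-fold larger there. With readings raised to 137 the ratio was 34.8-fold larger there for yknW, 23.2-fold for yknX, 29.0-fold for spo0M, 8.39-fold for yjoB and 9.32-fold for ydaH, but only 1.56-fold for ywnJ. As deposited these genes differed by 45.4-fold, 28.9-fold, 57.7-fold, 20.5-fold, 17.5-fold and 19.0-fold. The differences of dltA, dltB, dltC, dltD and dltE lay between 4.78-fold and 6.6-fold. In contrast, the ratios of ddl, divIC, divIB and minD were alike in the 2 strains, within 1.04-fold to 1.12-fold, and those of the sigV operon genes yrhL, yrhM and yrhK were 1.36-fold, 1.39-fold and 1.72-fold larger. The sigW probe was 2.35-fold lower in the wild type and 4.65-fold higher in the strain from which sigW was deleted.

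By list, the median difference in log2 ratio, strain lacking ECF sigma factors minus wild type, was 1.10 for SigW (27 of 53 members at least 2-fold larger, 2 smaller), 0.74 for SigM (20 of 57 larger, 1 smaller), 1.03 for SigX (10 of 19 larger, 1 smaller), 2.40 for D-alanylation (5 of 6 larger) and 2.19 for the sigY and ylaC operons (7 of 10 larger). Each of these lay at percentile 100 among random lists. Some of these lists overlap, since the 6 D-alanylation members are also in the SigX and SigM lists. The 8 own members of the SigX list had medians of -0.47 in the wild type and -0.48 in the deletion strain. Its 11 shared members had medians of 1.20 and 3.45, so the SigX difference came from these. With members above control level on both arrays the differences were 0.95 for SigW over 37 genes and 0.73 for SigM over 49 genes. With readings raised to 137 the differences were 0.48 for SigW (16 members at least 2-fold larger), 0.54 for SigM (14), 0.27 for SigX (6), 2.40 for D-alanylation (5) and 0.53 for the sigY and ylaC operons (4), each at percentile 100. The SigW value is that of pbpE, whose readings in the deletion strain were both raised to 137. Of the 5 largest single differences, those of yqjL and spo0M came from spots above control level on both arrays, while those of ytqB, yuaF and cotX were not above it in the deletion strain. Of the 5 smallest (yfkD, yddC, mpr, ykoX and ykpB), only yfkD was above control level on both arrays.

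Among the 2154 genes above control level on both arrays, 73 were at least 2-fold higher in both strains, against 4.97 for independent lists (product of the 2 counts over the number of genes). Another 50 were so only in the strain lacking the ECF sigma factors by this size limit and 14 only in the wild type. Members of the ECF lists, operon partners included, made up 4.87% of these genes (105 of 2154), 31 of the 73 (42.5%), 32 of the 50 (64.0%) and 0 of the 14. They were also 41 of the 54 genes whose ratio was at least 2-fold larger in the strain lacking the ECF sigma factors and 0 of the 11 with a ratio at least 2-fold smaller. Lower in both strains were 29 genes, against 1.58 for independent lists, and none of them belonged to an ECF list. Centred on the genes above control level, 95 were higher and 6 lower in both. Over all 4085 genes measured on both arrays, 539 were at least 2-fold higher and 128 lower in both (147.8 and 14.2 for independent lists), with a Pearson r of 0.68 and a Spearman rho of 0.75 across genes, which are not independent replicates. For the genes above control level on both arrays r was 0.80 and rho 0.83. Both arrays have the same dye order, and no dye swap was among the data used. An effect of dye, probe or IPTG common to both arrays would raise these overlaps and correlations without SigV. The excess over independent lists therefore does not measure a shared response to SigV.

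**Figure D3:**
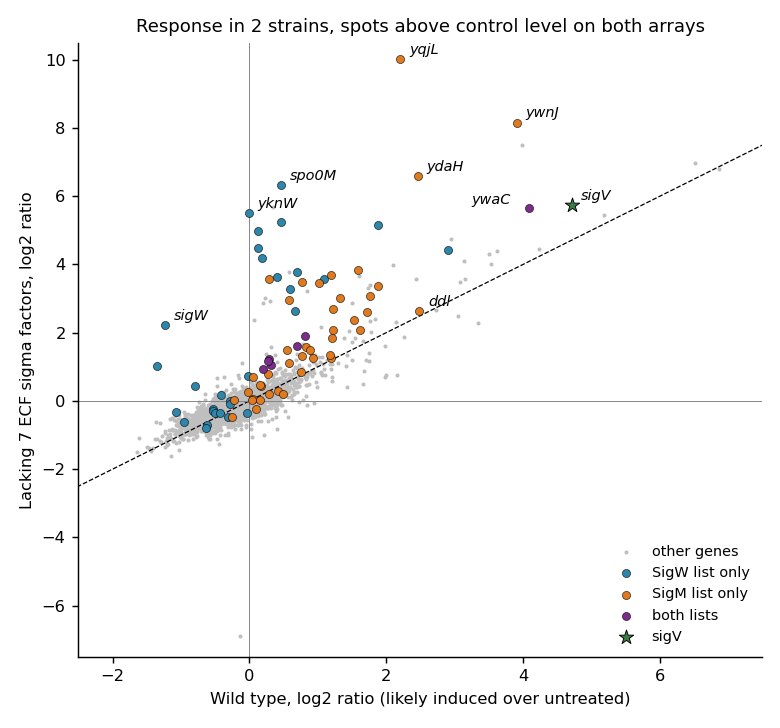
Log2 ratio (likely induced over untreated) in the strain lacking 7 ECF sigma factors against that in the wild type, for the 2154 genes above control level on both arrays. The members of the SigW and SigM lists are coloured, sigV is the star, and the dashed line marks equal ratios. Members such as yknW (-0.01 and 5.50) and spo0M (0.47 and 6.32) lie far above the line, and ddl (2.48 and 2.63) lies close to it.

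Among peptidoglycan synthesis genes, 3 of 24 in the wild type (ddl, murF and rodA) and 5 of 24 in the other strain (with mreB and murG in addition) were at least 2-fold higher, and the list medians were -0.29 and -0.25, at percentiles 4.66 and 10.96. Against lists matched on signal these percentiles were 45.5 and 54.9. In the deletion strain the mean of this list was positive, at 0.10. These 24 are the members found by present symbols, out of 31. With older symbols all 31 were found, and ywoA and ydaH were among the higher ones in both strains. Then 5 were at least 2-fold higher in the wild type and 7 in the deletion strain, with medians of -0.24 and -0.13. Of the 13 teichoic acid synthesis genes found by present symbols, out of 21, 1 passed the size limit, tagO in the wild type at 2.04-fold lower, which falls short of it after scaling (log2 ratio -0.97) or centring on the genes above control level (-0.81). The list medians were -0.51 and -0.19, at percentiles 1.265 (6.195 against lists matched on signal) and 26.8 (62.3 against such lists). With older symbols 20 members were found, of which 2 were higher and 2 lower in the wild type and 3 higher in the deletion strain, among them ywtF, at 3.29-fold and 6.04-fold. Neither the 10 pyrimidine genes in either strain nor the 45 ribosomal protein genes in the deletion strain held a gene at least 2-fold apart, and in the wild type 3 ribosomal protein genes were higher, of which rplJ and rplT were not above control level and rpmE was (2.07-fold). The ribosomal list had medians of -0.11 and -0.14, at percentiles 24.4 and 23.6 but 99.07 and 98.4 against lists matched on signal and 2.09 and 2.19 with readings raised, and the pyrimidine list of -0.10 and -0.21. The heat shock genes under HrcA and CtsR had medians of 0.19 and 0.13, at percentiles 81.0 and 82.9 but 99.95 and 99.5 against lists matched on signal, with 1 of 16 at least 2-fold higher, clpE in the deletion strain (2.18-fold). Of the 34 genes of the SigB general stress list 3 were lower in the wild type, among them csbX (2.30-fold), 3 others, all on spots not above control level, were higher and 1 lower in the deletion strain, and its medians were -0.39 and -0.23, at percentiles 0.33 and 9.72. Against lists matched on signal the SigB percentiles were 0.96 and 30.5. Motility and chemotaxis genes under SigD had 6 of 42 at least 2-fold lower in the wild type, among them lytC (2.31-fold) and fliG (2.27-fold), and 2 in the deletion strain, with medians of -0.15 and -0.25. These medians lay at percentiles 15.13 and 4.91, or 91.9 and 67.4 against lists matched on signal. For the mean of the list the percentiles were 0 and 0.15. Centred on the genes above control level, csbX, lytC and fliG in the wild type fell short of 2-fold, at log2 ratios of -0.98, -0.99 and -0.97, and so did fliG in the deletion strain (-0.89). No SigB or SigD list member in the wild type and 1 of each list in the deletion strain stayed at least 2-fold lower with that centring.

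The lists of iron and purine genes lay low on both arrays. The Fur list, genes of iron uptake, had medians of -0.60 and -0.67 over 22 members, at percentiles 0.01 and 0. Of these 4 were at least 2-fold lower and 2 higher in the wild type, and 1 was lower in the deletion strain. Centred on the genes above control level, no member stayed at least 2-fold lower on either array. With that centring the list had 2 members higher in the wild type and 1 in the deletion strain. Its member dhbC was 2.5-fold higher in the wild type from a spot not above control level, and fhuB was lower by 2.16-fold and 2.27-fold, which fell short of 2-fold when centred on the genes above control level (log2 ratios -0.89 and -0.99) and in the wild type also with readings raised (1.25-fold). Purine synthesis genes had medians of -0.53 and -0.56 over 18 members, at percentiles 0.09 and 0.05, with purK lower by 1.76-fold and 2.16-fold (log2 ratio of -0.91 in the deletion strain when centred so). Early sporulation genes had medians of -0.03 and -0.37, competence genes of 0.00 and -0.04, SOS and PBSX prophage genes of 0.02 and 0.00, PhoP genes of 0.21 and 0.01 and WalR genes of -0.11 and -0.27. The means of the sporulation and competence lists were positive in both strains, at 0.80 and 0.31 and at 0.31 and 0.33, and in the deletion strain those of the SOS and WalR lists were 0.19 and 0.08. Of 16 sporulation genes 6 were at least 2-fold higher and 1 lower in the wild type and 4 and 2 in the deletion strain, and of 22 competence genes 4 and 2 and then 5 and 2. The higher ones, such as sigG, comGD and comC, were all on spots not above control level. For the two-component envelope stress list 2 of 16 members were found by their present symbols, yxdL (3.16-fold and 3.36-fold higher) and yxdM (2.12-fold lower and 2.08-fold higher, the latter from a spot not above control level and the former short of 2-fold when centred, at -0.86), and for the biofilm list 2 of 20, tasA and sipW, at log2 ratios of -0.43 and -0.81 in the wild type and 0.01 and -0.40 in the deletion strain. With older symbols all 20 biofilm members were found, with medians of 0.08 and -0.11. In the wild type 4 were at least 2-fold higher, none on a spot above control level, and in the deletion strain 1, on such a spot.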

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

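All tests on explanations in this part were chosen after the results were seen, except the scaling of both arrays to 1 robust spread.

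The probes of 43 genes were at least 2-fold higher on 1 array and at least 2-fold lower on the other, and with 1 array per strain none of these differences was tested. Above control level on both arrays were 2 of them, sigW and yeaA, the latter with a log2 difference of 2.37. For the 5 among the genes that the rule selected the log2 difference, deletion strain minus wild type, was 3.45 for sigW, -2.25 for sigZ, -6.25 for yddC, 6.86 for ytqB and 2.13 for yxdM. The spots of sigZ, yddC and ytqB were not above control level on either array, that of yxdM was above it in the wild type, and that of sigW was above it on both.

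The control spots, which the comparisons do not use, carried ratios as large as those of many genes. In the wild type 13 of 22 were at least 2-fold higher, with a median of 2.63-fold and a highest value of 26.5-fold, and in the deletion strain 15 of 22, with a median of 2.5-fold and a highest value of 25-fold. A candidate explanation for the excess of higher over lower genes (806 against 248, and 754 against 240) is that spots near background read higher in the induced channel. The share of control spots at least 2-fold higher was 59.1% and 68.2%, and the exact intervals (36.4% to 79.3% and 45.1% to 86.1%) lie above the 4.25% and 6.19% among genes above control level. A dye effect at low signal and a true rise of weakly expressed genes stay open for single genes, since no dye swap was analysed here, and no biological explanation was tested.

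The larger ratios of the SigW and SigM lists in the strain lacking the ECF sigma factors were weighed against technical explanations. Scaling all genes to 1 robust spread gave median differences of 1.21 for SigW and 0.84 for SigM, but this is no test of a wider spread, since by that measure the array was the narrower one (0.65 against 0.74 in the wild type). Among genes above control level on both arrays its standard deviation was larger (0.92 against 0.67). After scaling these genes to 1 standard deviation the SigW difference was 0.67 (95% interval 0.55 to 1.78, random lists up to 0.24), which argues against the larger deviation as the whole cause. The SigM difference was 0.28 (0.20 to 0.57, random lists up to 0.22). It lay at percentile 99.92 among random lists but cannot decide the question for that list, because its interval starts below their upper bound. The deviation used for scaling includes the members of both lists. ECF list members were 41 of the 54 such genes with a ratio at least 2-fold larger in the deletion strain. The scaling thus removes a part of the difference under test. Spots near background are argued against as the whole cause by differences of 0.95 and 0.73 among members above control level on both arrays (random lists up to 0.13 and 0.12) and of 0.48 and 0.54 with all readings under 137 raised to it (up to 0.02 and 0.01), although the raised SigW median in the deletion strain was 0. Another, biological in kind, is a lower untreated level where the sigma factors that drive these genes are missing, and the untreated readings of that strain over wild type had medians of -1.86 for SigW (32 members, random lists -0.37 to 0.60) and -0.57 for SigM (39 members, -0.32 to 0.57), whereas the induced readings, 0.25 and 0.46, lay within the random range. This may account for the pattern as a hypothesis, but the readings are lower bounds from separate arrays with unstated normalization, and a stronger induction of sigV in that strain (2.03-fold larger ratio) stays open.

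Probes of deleted ECF sigma factor genes gave ratios of at least 2-fold in the strain lacking them. For sigW and ylaC, spots near background are argued against, since the lower of their brighter-channel readings was 311 and the highest control spot of that array stood at 137. This argument is limited, because 1 random-sequence control spot reached 976 on the wild type array. The untreated readings of both probes were also under 137, with raised ratios of 2.85-fold for sigW and 2.27-fold for ylaC. For sigM the reading was 59, within the range of the control spots, so that background may account for it. Parts of the genes left in place and hybridisation of neighbouring transcripts stay open for sigW and ylaC, because the probe positions and deletion ends are not given in the sources used here.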

How the results depend on the processing

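Tests restricted to genes above control level, centred on their median, matched on signal, extended by older symbols or with readings raised to 137 were chosen after the data were examined. The planned filter on dim probes was not run, since intensities were not used here, and counting each probe on its own changes nothing with 1 probe per gene. No paired analysis was possible because each strain has 1 array. The cause was not tested for the changes below unless the setting itself leaves out genes. Of the alternative values of the counts and the correlation, 69 stayed within 1.5 times the main count or the interval of r and 28 did not. Of the values of named genes 849 stayed on the same side of 2-fold and 139 did not, 100 of these with raised readings, 25 on centring on genes above control level, 8 on scaling and 6 on centring on all genes.

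Restriction to genes above control level, which leaves out many genes by construction, gave 104 higher (806 over all genes) and 80 lower (248) in the wild type, 166 (754) and 53 (240) in the deletion strain, 54 with a larger (343) and 11 with a smaller ratio (398) there, 73 higher (539) and 29 lower (128) in both, and an r of 0.80 (0.68). At 1.5-fold the lower genes numbered 705, 670 and, in both strains, 438, and at 3-fold 117, 124 and 52, with 226 larger and 253 smaller ratios. Centring on the genes above control level, a shift of 0.22 and 0.20, left 161, 159 and 79 lower genes. With readings under 137 raised to it, which sets dim genes to a ratio of 1, 72 genes were higher and 74 lower in the wild type and 114 and 46 in the deletion strain, 61 had a larger and 19 a smaller ratio there, and 52 were higher and 24 lower in both. The SigW median in the deletion strain was then 0 (1.11), percentile 59.215 (100), the SigX percentile in the wild type 59.495 and that of D-alanylation 100. Older symbols gave sigV operon medians of 3.57 and 4.2 over 4 genes (4.16 and 5.06 over 2) and turned the two-component median in the deletion strain from 1.40 to -0.29 over 16 genes. With 1 value per run of neighbours the SigM median in the wild type was 0.98 (0.70) and the SigW median in the deletion strain 2.85 (1.11). In the wild type the SigW percentile of 43.0 became 97.53 with matched random lists and 1.35 without shared members, the D-alanylation percentile of 96.7 became 100 with matched lists, and the SigX percentile of 98.5 became 97.1 with random runs, 68.05 for the mean and 3.85 without shared members. Without shared members the SigX list in the deletion strain turned from 1.25 to -0.48, percentile 3.45 (99.96). Lists matched on signal also changed the wild type percentiles of the ECF sigma factor genes (99.12), the sigY and ylaC operons (98.3), heat shock (99.95), ribosomal (99.07), PhoP (97.925) and teichoic acid genes (6.195) and the deletion strain percentiles of heat shock (99.51), ribosomal (98.435) and early sporulation genes (0.64). Raised readings changed 11 percentiles of lists other than SigM, SigW, SigX and D-alanylation, in the wild type to 99.92 for operon partners, 99.94 for the sigY and ylaC operons and for PhoP, 99.99 for heat shock, 0.91 for peptidoglycan, 1.1 for motility and 2.09 for ribosomal genes, and in the deletion strain to 64.835 for ECF sigma factor, 99.96 for heat shock, 0.26 for motility and 2.19 for ribosomal genes. The SigM list in both strains stayed at percentile 99.15 or above in every setting run, and the SigW list in the deletion strain at 100 in all but the raised one.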

Other observations

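All tests and groupings in this part were chosen after the values were seen. The ribose uptake operon was lower in both strains without belonging to any list. All 6 genes in a row, rbsR, rbsK, rbsD, rbsA, rbsC and rbsB, were above control level on both arrays and lay between 2.04-fold and 2.72-fold lower in the wild type and between 2.28-fold and 3.05-fold lower in the deletion strain. With readings under 137 raised to it, rbsR in the wild type was 1.27-fold lower and rbsK in the deletion strain 2.22-fold. Centred on the genes above control level, rbsK and rbsD stayed at least 2-fold lower on both arrays, whereas rbsR, rbsA, rbsC and rbsB in the wild type (log2 ratios -0.92, -0.81, -0.82 and -0.88) and rbsB in the deletion strain (-0.99) fell short. Other genes lower on both arrays were qoxA and qoxB of the terminal quinol oxidase (2.56-fold and 2.61-fold in the wild type, 2.17-fold and 2.19-fold in the deletion strain), lytB and lytC of an autolysin operon, the iron-siderophore uptake genes yclN and yclO, the manganese uptake gene mntB (2.48-fold and 2.25-fold) and srfAA of surfactin synthesis (3.12-fold and 2.82-fold). Of these, srfAA alone stayed at least 2-fold lower on both arrays with that centring. Short of it were lytB, lytC and yclO in the wild type (-0.97, -0.99 and -0.998) and qoxA, qoxB, mntB, yclN and yclO in the deletion strain (-0.92, -0.93, -0.97, -0.84 and -0.97).

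Higher on both arrays outside the ECF lists were mmgD and mmgE, of the methylcitrate pathway (36.4-fold and 18.7-fold in the wild type, 43.4-fold and 21.9-fold in the deletion strain), ycgQ and ycgR (11.3-fold and 5.39-fold, then 19.9-fold and 11.9-fold), yheD and yheE (15.8-fold and 4.30-fold, then 180.7-fold and 15.7-fold), yocL and yocM (8.47-fold and 3.39-fold, then 11.1-fold and 5.06-fold), and ydfK and ydfL (4.42-fold and 10.1-fold, then 4.93-fold and 4.85-fold). The neighbours yxeO, yxeP, yxeQ and yxeR stood out in the other direction, with log2 ratios of 1.98, 2.33, 2.16 and 1.99 in the wild type and 0.70, 0.60, 0.76 and 0.76 in the deletion strain. The gene yvdS was 1.27-fold higher in the wild type and 51.7-fold higher in the deletion strain. Many of these sizes rest on untreated readings of 137 or less. With those raised to 137 the ratios were 12.5-fold and 3.80-fold for mmgD in the wild type and the deletion strain, 7.25-fold and 1.44-fold for mmgE, 11.3-fold and 5.96-fold for ycgQ, 3.69-fold and 3.96-fold for yheD, 3.07-fold and 1.72-fold for yheE, 6.36-fold and 11.1-fold for yocL, 3.71-fold and 2.74-fold for ydfK, 3.02-fold and 4.85-fold for ydfL and 6.04-fold for yvdS in the deletion strain. The log2 ratios of yxeO and yxeQ in the wild type were then 1.56 and 0.68, and that of yxeP in the deletion strain was 0.

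Some genes had almost no signal on 1 of the arrays. A brighter-channel reading of at most 20 on an array, with over 1000 on the other, was found for 33 genes in the wild type, among them dnaN and polA, and for 10 genes in the deletion strain. Among these 10 were the deleted sigY and also prs, which was 16-fold lower there (1 against 16) and had readings of 1045 and 1937 in the wild type. The ratios of such genes rest on few units of signal, unless a large common factor was lost in the reduced ratio.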
